A study of Mus musculus with 8 samples.

How the data were processed

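Total RNA from murine skeletal myoblasts was measured on 8 Illumina WG-6 v2.0 BeadChip arrays, with 1 array per sample. The samples formed 4 groups of 2 biological replicates: cells given a scrambled control siRNA or an siRNA against G9a (siG9a), each at day 0 and at day 1. The labels do not say from which event the days were counted. Replicate numbers were taken from the sample titles.

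The values used were the processed table deposited with the series, 45281 probes on each of the 8 arrays. The deposited values are taken as log2: they are logarithms relative to a level of each probe's own, and the base is not stated. Base 10 would turn the widest range within a probe, 6.88 units, into a fold change that the array cannot measure, but a natural logarithm cannot be excluded, and every log2 fold change and percentage below rests on base 2. The level of each probe was near the middle of its values, and the median over these 8 arrays was 0 within 1e-05 in 32.9% of probes. Differences between arrays are not affected by such a level. The software, background correction, normalization and filters that the authors applied are not given in the sources used here. A second deposited table, with unnormalized signal and detection values in 16 columns named SAMPLE 1 to SAMPLE 8, could not be matched to samples by name and was not used here. Settings that need its signal or detection values, including background corrections, other between-array normalizations, detection filters and an intensity trend in the variance, were not run. No dim probes were removed, since values relative to each probe's own level carry no absolute intensity. For arrays, the number of arrays limits the precision, and the signal over background is unknown here.

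Probe names came from the platform's gene table. Symbols were updated through the Entrez gene ID for 28620 probes and through the transcript accession for 2637, and 4527 kept the symbol of the platform table. In total 35784 probes carried 1 symbol and 9497 carried none. For each of the 21946 named genes the probe with the largest standard deviation over all 8 arrays was kept, without regard to group, and unnamed probes were kept singly, which gave 31443 features. Where other probes of a named gene moved the other way, this is said.

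Group means were compared in limma 3.58.1 under R 4.3.3 with 1 linear model of the 4 group means over all 8 arrays, followed by empirical Bayes moderation without an intensity trend (4 residual and 4.59 prior degrees of freedom). Standard errors (SE) are the moderated ones of that model. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all 31443 features. The 6 comparisons were siG9a minus control at day 0, at day 1 and as the mean of both days, day 1 minus day 0 in control and in siG9a, and the difference between the siG9a effects of the 2 days (the interaction). An exact two-sided permutation test of 2 arrays against 2 cannot give a p under 0.333, so none was used for single genes. The replicate numbers paired the samples: over the 6 pairs of groups, the deviations of the replicates from their group means correlated across features with r between 0.613 and 0.865. The same model with the replicate number as an additive term (the blocked fit, 3 residual and 5.87 prior degrees of freedom) is therefore given beside results that it changes.

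Gene lists (29 lists, 1000 entries, of which 930 were measured) were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists within a comparison. Beside it stand camera with a correlation estimated for each list and fry, which tests whether the genes of a list move on balance one way. The gene lists, the comparisons, the threshold and the rule for naming genes were set before the data were examined. That rule named Ehmt2 and Ehmt1, up to 12 genes with the largest rise and 12 with the largest fall among called genes whose groups did not overlap (or, with none called, the 5 smallest p each way), up to 6 members of each list with the smallest p, the members of the regulator lists, and 10 cell cycle and muscle genes. The choice of probe by standard deviation, the use of the processed values and the moderation without a trend were set after the form of the values was seen.

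The model was tested on changes added to simulated arrays. These were built from the means of the blocked fit, with siG9a set equal to control. Random noise of that fit's spread was added, independent between features and arrays. In the comparison of siG9a with control at day 0 it called 0% of changes of 0.5 log2 units, 1.49% of changes of 1 unit and 69.7% of changes of 2 units, and the blocked fit called 65.7% of changes of 1 unit and 92.4% of changes of 2 units. Because the simulated values followed the blocked fit's own model, its shares are a best case. A lack of called features therefore does not exclude changes of 1 or 2 units. Alternatives were median centring of each array, the blocked fit, array weights, a fit on the arrays of the comparison alone, all probes, a 1.5-fold minimum, an adjusted p under 0.10, and each array left out in turn. Added after seeing the data were robust moderation, the upper part of the features by standard deviation, named features alone, the mean of a gene's probes, and a limma test of the 4 differences between siG9a and control arrays of the same day and replicate (3 residual and 16.9 prior degrees of freedom), with both forms of camera on these differences, the same test with the replicate as a correlated block, and the same test on the 2 replicate means. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.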

Results

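Transcript levels were measured in murine skeletal myoblasts that received a scrambled control siRNA or an siRNA against G9a, the histone H3 lysine 9 methyltransferase encoded by Ehmt2. There were 2 control and 2 siG9a samples at day 0 and the same numbers at day 1, 8 arrays in all, and the series title places the work under cell cycle regulation in muscle cells. Values are log2 units under the stated assumption on the base, differences are given ± SE from limma with n = 2 arrays per group, and the number of arrays limits their precision. Array medians lay between -0.15 and 0.11, with all 4 arrays of replicate 1 below 0 and all 4 of replicate 2 above 0. The replicates also differed in gene lists: the median of 48 sarcomere and contraction genes was lower in replicate 2 than in replicate 1, by -1.91 at day 0 and -1.26 at day 1. Other lists were higher in replicate 2, extracellular matrix by 0.42 and 0.59, hypoxia and glycolysis by 0.71 and 0.34, and fibroblast markers by 0.23 and 0.66. Inflammation genes (0.412 and 0.396) and endothelial (0.307 and 0.239), adipocyte (0.285 and 0.218) and macrophage markers (0.235 and 0.277) were higher too. The fibroblast shift at day 0 was therefore not particular to that list.

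The first question was how far the siRNA lowered its target. Ehmt2 was lower in siG9a by -1.67 ± 0.27 at day 0 and by -1.34 ± 0.27 at day 1, on probe ILMN_3147724. In the replicate pairs this left 24.1% and 41.2% of the control level at day 0 and 30.4% and 51.3% at day 1. A second Ehmt2 probe, ILMN_2705367, gave -1.72 and -1.31, while the remaining probe, ILMN_2615204, gave only -0.14 and -0.16. The platform assigns this last probe to a different Ehmt2 transcript record from the one that the other probes share. Whether that accounts for its smaller change was not tested. Ehmt1, which encodes the partner methyltransferase GLP, differed by -0.093 ± 0.38 at day 0 and -0.070 ± 0.38 at day 1. Its other probe, ILMN_2633604, went the other way, by 0.067 and 0.11. In limma, Ehmt2 had the smallest p of the 23 measured H3K9 methylation genes and was the 1 member that passed when adjusted over the list alone at each day. Over all 31443 features its adjusted p was 1 at both days. With the blocked fit the adjusted p was 0.487 at day 0 and 0.993 at day 1.

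**Figure D1:**
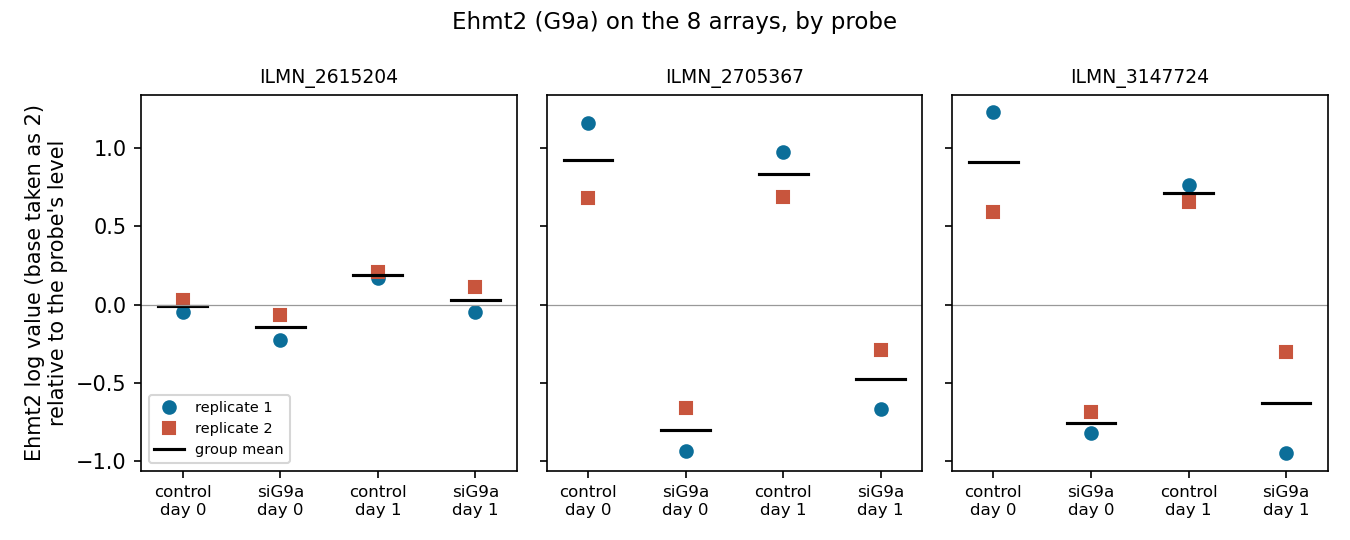
Ehmt2 log values (base taken as 2, relative to each probe's own level) on each of the 8 arrays for 3 probes, with points for the replicates and bars for the group means. On ILMN_3147724 and ILMN_2705367 every siG9a array lay below every control array, whereas the group means of ILMN_2615204 differed by -0.14 at day 0 and -0.16 at day 1.

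At day 0, the comparison of siG9a with control asked what differed in cells given the siRNA against G9a. Genes of the sarcomere were higher in siG9a as a group, with a list median of 0.46 and 38 of 48 members higher, and genes of DNA replication were lower, with a median of -0.20 for the G1/S list and 48 of 51 members lower. Among sarcomere genes, Atp2a1, the fast-muscle calcium pump, was higher by 0.98 ± 0.83 and Actn3, fast-fibre alpha-actinin, by 0.80 ± 0.89. Among replication genes, Gins1, a subunit of the replicative helicase, was lower by -0.45 ± 0.28 and Rfc4, a clamp loader subunit, by -0.34 ± 0.18. The extracellular matrix list was higher (median 0.15, 32 of 44 members), with the matrix glycoprotein tenascin-C (Tnc) at 1.02 ± 0.60, and so was the fusion, adhesion and neuromuscular junction list (median 0.14, 18 of 27), with alpha-sarcoglycan (Sgca) at 0.85 ± 0.40. Mitotic genes were lower (median -0.15, 46 of 51), among them the kinase Aurkb at -0.35 ± 0.23.

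None of these genes passed the test singly at day 0, nor when adjusted over the list alone. In the blocked fit, adjusted over their list alone, Actn3 (adjusted p = 0.017), Sgca (adjusted p = 0.0254) and Itga7 (0.61, adjusted p = 0.0338) were called higher and Kirrel3 (-0.38, adjusted p = 0.0431) lower. Itga7 and Kirrel3 were named after their values were seen. In camera, the adjusted p was 1.1e-06 for the sarcomere list, 1.1e-06 for G1/S, 7.7e-05 for extracellular matrix, 0.0059 for G2/M and 0.0114 for fusion. Autophagy and lysosome, p53 target and respiratory chain genes were also called higher, and ribosomal protein and H3K9 methylation genes lower, 10 of 29 lists in all. The H3K9 methylation list includes Ehmt2, the target of the siRNA, so its call is partly built in. The list without Ehmt2 was not tested. With an estimated correlation no list was called, with an adjusted p = 0.81 for the sarcomere, G1/S, G2/M, fusion and extracellular matrix lists and between 0.8 and 0.958 for the others, and fry called 0 lists. In the blocked fit the H3K9 methylation list was no longer called (adjusted p = 0.0984). The sarcomere list stood at 0.87 in replicate 1 and 0.14 in replicate 2, and its median turned to -0.43 without siG9a replicate 1 and -0.089 without control replicate 2. The fusion list turned to -0.19 and -0.11 without the same arrays, and extracellular matrix to -0.14 without control replicate 1 and -0.11 without siG9a replicate 2. Leaving out 1 array breaks a replicate pair, so the replicate difference (-1.91 for the sarcomere list at day 0) enters these medians. Each of these lists had a median above 0 in both replicate pairs. The turns alone do not show that 1 array carried a shift, and this applies wherever an array is left out below. Median centring ended 7 of the 10 list calls and kept those of the sarcomere, G1/S and extracellular matrix lists. Among the ended calls were those of the fusion list (median 0.177 after centring, adjusted p = 0.315 in camera) and the G2/M list (median -0.107, adjusted p = 0.0513).

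Over single genes at day 0, limma called 0 of 31443 features, with 123 at an unadjusted p under 0.05, and the blocked fit also called 0, with 1728. By chance alone 1572 were expected in either fit, if p-values without an effect are uniform. Without the block, the residual spread includes the replicate difference, which makes the p-values too large. A count of 123 therefore does not show fewer changes than chance. The same limit applies to the unblocked counts of the other siG9a comparisons below. The smallest p among higher genes, none past the threshold, were those of Lrp11 (0.93 ± 0.19), Scamp5 (0.67 ± 0.17), Susd1 (0.74 ± 0.19), Angpt2 (0.64 ± 0.17), an angiopoietin, and Fcgr4 (1.09 ± 0.30), an Fc receptor. The second Angpt2 probe went the other way. Among lower genes they included those of Ehmt2 itself, Tead2 (-0.96 ± 0.22), a TEAD transcription factor, Smim11 (-1.12 ± 0.30) and Foxc2 (-0.67 ± 0.18), a forkhead factor. Cyclin D1 (Ccnd1) stood at -0.41 ± 0.28, the CDK inhibitor p57 (Cdkn1c) at -0.56 ± 0.29, Rb1, the retinoblastoma protein gene, at 0.47 ± 0.35, myogenin (Myog) at 0.66 ± 1.07 and embryonic myosin (Myh3) at 0.59 ± 0.98. Klf4 stood at -0.64 ± 0.23 and the stress-responsive kinase gene Plk2 at -0.70 ± 0.30. In the blocked fit, adjusted over its list alone, Plk2 was called lower (adjusted p = 0.00277). Fgf21 (0.91, adjusted p = 0.0239) and Fst (0.68, adjusted p = 0.0473) were called higher in the same way.

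**Figure D2:**
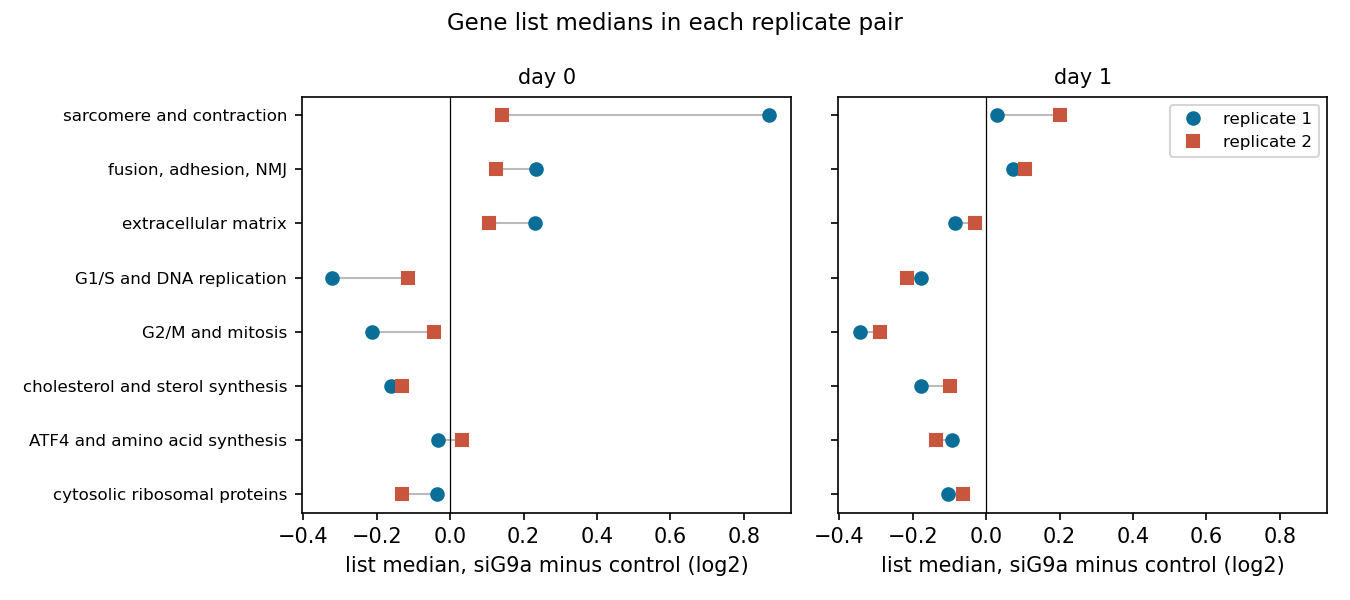
Medians of 8 gene lists (siG9a minus control, log2 units) in replicate pair 1 (circles) and replicate pair 2 (squares), at day 0 and day 1. The G2/M list lay at -0.34 and -0.29 at day 1, and the sarcomere list at 0.87 and 0.14 at day 0.

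At day 1, the same comparison asked what differed one day later. Genes of mitosis were lower in siG9a, with a list median of -0.33 and 39 of 51 members lower, and both replicate pairs were close together at -0.34 and -0.29. Plk1, the polo kinase of mitotic entry, was lower by -0.65 ± 0.26, Nusap1, a spindle protein, by -0.58 ± 0.19, Cdca2 by -0.46 ± 0.20, Aurkb by -0.46 ± 0.23 and Cdc25c, the phosphatase that activates CDK1, by -0.40 ± 0.16. The G1/S list was lower too (median -0.22, 38 of 51), with Ccnd1 at -0.78 ± 0.28 and the chromatin assembly factor gene Chaf1b at -0.45 ± 0.30. Genes of cholesterol synthesis were lower in 20 of 23 cases (median -0.13), among them Stard4 at -0.53 ± 0.27, Cyp51 at -0.45 ± 0.41 and Nsdhl at -0.42 ± 0.29. The ATF4 and amino acid synthesis list had a median of -0.12 (22 of 30 lower), with Ddit3 at -0.42 ± 0.20 and Trib3 at -0.40 ± 0.25, and ribosomal protein genes one of -0.086 (22 of 28 lower), with Rps12 at -0.28 ± 0.25. Probes of Nusap1 and Cdc25c other than those used did not all go the same way.

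Camera called 9 of 29 lists at day 1, all lower, with an adjusted p of 4.6e-22 for G2/M, 4.9e-10 for G1/S, 1.4e-05 for cholesterol synthesis, 0.000202 for ribosomal proteins and 0.00132 for ATF4. CDK inhibitor, ribosome biogenesis, chromatin regulator and, with Ehmt2 itself among them, H3K9 methylation genes made up the rest. The last of these was lost in the blocked fit (adjusted p = 0.109), which called extracellular matrix (adjusted p = 0.0126) and glycolysis genes (adjusted p = 0.0163) lower instead, with an adjusted p = 0.431 and 0.698 with an estimated correlation in that fit. With an estimated correlation the adjusted p = 0.29 for G2/M and 0.494 for each of the other called lists, so none was called, and fry called 0. The sarcomere list, with a median of 0.10, was not called (adjusted p = 0.5). Without control replicate 1 the medians turned to 0.0092 for G1/S, 0.13 for cholesterol synthesis and 0.11 for ATF4, without siG9a replicate 2 to 0.0039, 0.021 and 0.14, and the ribosomal protein median turned to 0.038 without siG9a replicate 1 and 0.010 without control replicate 2. Median centring ended 5 of the 9 list calls, among them that of the ATF4 list (median -0.158 after centring, adjusted p = 0.104), and kept those of G2/M, G1/S, cholesterol synthesis and ribosomal proteins.

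Over single genes at day 1, limma called 0 features, with 54 at an unadjusted p under 0.05, and the blocked fit 0, with 1195, where chance alone gives 1572. Again with no gene past the threshold, the smallest p among higher genes belonged to Lrp11 (0.88 ± 0.19), the placental hormone gene Prl2c4 (0.80 ± 0.26), the serpins Serpinb9g (1.27 ± 0.41) and Serping1 (0.63 ± 0.21), and Serpinb9d. Among lower genes they belonged to Ehmt2, Nusap1, the CDK-associated phosphatase gene Cdkn3 (-0.57 ± 0.19), Ccnd1 and Fgd1 (-0.48 ± 0.17). Cdkn1c stood at -0.67 ± 0.29. No list of lineage markers other than muscle (fibroblast, adipocyte, macrophage and leukocyte, endothelial, neuronal) was called by camera at either day. Neither were the germline genes (median -0.025 at day 0 and 0.019 at day 1), imprinted genes (-0.039 and -0.047) or interferon-stimulated genes (-0.011 and 0.076), although Gbp2, an interferon-induced GTPase, stood at 1.07 ± 0.55 at day 0. How many members of these lists were detected is unknown here, so medians near 0 do not show that no member changed.

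Averaged over both days, siG9a cells had lower cell cycle genes and higher sarcomere genes. The G2/M list had a median of -0.25 (44 of 51 lower), G1/S one of -0.21 (45 of 51 lower), cholesterol synthesis one of -0.17 (18 of 23 lower) and the sarcomere list one of 0.34 (43 of 48 higher). Ccnd1 was lower in all 4 replicate pairs, by -0.60 ± 0.20 on average, and so were Aurkb (-0.41 ± 0.16), Tpx2 (-0.36 ± 0.15), a spindle assembly factor, Gins1 (-0.39 ± 0.20) and Cdkn1c (-0.61 ± 0.21). Lrp11 (0.90 ± 0.13), Angpt2 (0.55 ± 0.12), Apol9b (0.62 ± 0.17), Scamp5 (0.44 ± 0.12) and Fcgr4 (0.78 ± 0.21) had the smallest p among higher genes, and Ehmt2, Tead2 (-0.67 ± 0.15), Rbms3 (-0.43 ± 0.11), Pdlim2 (-0.57 ± 0.15) and Twist2 (-0.43 ± 0.13), a repressor of myogenic transcription, among lower ones. Camera called 9 of 29 lists, with an adjusted p of 1.3e-17 for G2/M, 4.2e-15 for G1/S, 4.5e-05 for the sarcomere and 7.0e-05 for cholesterol synthesis. With an estimated correlation the adjusted p = 0.423, 0.423, 0.714 and 0.587, and fry called 0. The blocked fit also called extracellular matrix genes higher (median 0.032, adjusted p = 0.0323, and adjusted p = 0.517 with an estimated correlation in that fit). Median centring ended 4 of the 9 calls and kept those of G2/M, G1/S, the sarcomere, cholesterol synthesis and ribosomal proteins. The sarcomere median turned to -0.13 without siG9a day 0 replicate 1 and to -0.0064 without siG9a day 1 replicate 1.

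Limma called 0 features over both days, with 148 at an unadjusted p under 0.05 where chance alone gives 1572, and the blocked fit called 0, with 1540 and a smallest adjusted p of 0.164. Adjusted over a list alone, the blocked fit called Ehmt2, Plk2 (adjusted p = 0.00146), Thbs2 and Cdkn1c (adjusted p = 0.0499 in the CDK inhibitor list) lower. It called Actn3, Sgca, Fst and Tspan32 higher, and no member of the G1/S or G2/M list. The 4 differences within day and replicate, from 2 biological replicates, were tested instead, which removes what the arrays of a pair share and was chosen after seeing the data. Limma then called 256 features, 120 higher and 136 lower, of which 247 had the same sign in all 4 pairs, and 157 features after median centring. Ehmt2 passed with a difference of -1.50 (adjusted p = 1.1e-06), as did Lrp11, Angpt2, Apol9b, Tead2, Pdlim2, Plk2, Cdkn1c and Ccnd1. Across features, the siG9a effects of the 2 days, which share replicate numbers but no arrays, correlated with a Pearson coefficient r = 0.15 and a Spearman coefficient of 0.0457, and 48.3% had the same sign. Features are not independent replicates, and r lay between -0.021 (without siG9a day 1 replicate 1) and 0.188 when single arrays were left out.

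In control cells, the change from day 0 to day 1 gives the course against which the knockdown is read. Cdkn1c, the CDK inhibitor p57, rose most, by 5.78 ± 0.29, together with Fgf21 (4.995 ± 0.73), a secreted stress hormone, C1qtnf3 (4.22 ± 0.68), Asb2 (4.18 ± 0.55), a ubiquitin ligase subunit of differentiating muscle, Unc45b (4.18 ± 0.77), the muscle myosin chaperone, and Fndc5 (3.66 ± 0.46), the irisin precursor gene. The proliferin genes fell most, Prl2c3 by -4.32 ± 0.26, Prl2c4 by -4.30 ± 0.26 and Prl2c2 by -4.12 ± 0.29, followed by the water channel gene Aqp1 (-3.09 ± 0.30) and the quinone reductase gene Nqo1 (-3.06 ± 0.33). Id1 (-2.60 ± 0.35) and Id3 (-2.33 ± 0.20), inhibitors of the myogenic bHLH factors, fell as well. Ramp2 (3.31 ± 0.30), Tgm2 (3.10 ± 0.35), Ogn (2.88 ± 0.21), Rbfox1 (2.65 ± 0.37), a splicing regulator of muscle, and Sort1 (2.50 ± 0.44) were among the other large rises, and Pcolce2 (-2.71 ± 0.44), H2ac21 (-2.34 ± 0.43), a histone H2A gene, and Ly6c1 (-2.20 ± 0.26) among the other falls.

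Cell cycle genes fell together in control cells. The G2/M list had a median of -1.43 with 49 of 51 members lower and 21 called (35 adjusted over the list alone), among them Aurkb (-1.90 ± 0.23), Birc5 (-2.05 ± 0.27), Plk1 (-1.94 ± 0.26) and Cdc25c (-1.49 ± 0.16). The G1/S list had a median of -1.31 with 47 of 51 lower and 15 called (36 lower and 1 higher adjusted over the list alone), among them Ccnd1 (-2.09 ± 0.28), Cdt1 (-1.81 ± 0.22), a replication licensing factor, and Tyms (-1.84 ± 0.29), thymidylate synthase. Rbl1, the pocket protein p107, fell (-1.45 ± 0.26), whereas Rb1 stood at 1.68 ± 0.35 (adjusted p = 0.0693, blocked 0.000179) and E2f1 at -1.04 ± 0.31 (adjusted p = 0.238, blocked 0.04). Cdkn1a, the CDK inhibitor p21, stood at 2.28 ± 0.73 (adjusted p = 0.289, blocked 0.00035).

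All 48 sarcomere genes were higher at day 1 in control cells, with a median of 2.94 (47 after median centring, with Neb at -0.0051). Of these 1 was called over all features, Unc45b, and 27 when adjusted over the list alone, while the blocked fit called 37. Atp2a1 (4.28 ± 0.83, adjusted p = 0.0555), Myl4 (3.82 ± 0.75, adjusted p = 0.057), a fetal myosin light chain, and Myh3 (3.80 ± 0.98, adjusted p = 0.149) passed in the blocked fit alone, and so did Myog (3.92 ± 1.07, adjusted p = 0.183), Mef2c (2.24 ± 0.71), Myod1 (1.17 ± 0.78) and Ccnd3 (0.83 ± 0.48), the cyclin D3 gene. The fusion list had a median of 1.04, with the fusogen Mymk at 3.76 ± 1.07 and 0 members called (8 higher and 1 lower adjusted over the list alone, 16 higher and 1 lower in the blocked fit). Sox8 rose by 1.84 ± 0.25. In the imprinted list (median 0.16, 21 of 28 higher) Cdkn1c passed, with Igf2 at 3.86 ± 0.77 and Mest at 2.28 ± 0.67 short of the threshold, and in the ATF4 list (median 0.40, 24 of 30 higher) Fgf21, Trib3 (1.65 ± 0.25) and Nupr1 (1.75 ± 0.25) rose while Shmt1 fell (-1.30 ± 0.20).

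Limma called 353 features in control cells, 114 higher and 239 lower, and the blocked fit called 2775, among them all 353. The count was 7 without control day 0 replicate 1, 25 without control day 0 replicate 2, 141 without control day 1 replicate 1, 80 without control day 1 replicate 2 and 92 after median centring. Camera called 11 lists, with an adjusted p of 7.4e-48 for G2/M, 2.3e-41 for G1/S, 1.8e-31 for the sarcomere, 5.9e-09 for fusion, 1.8e-07 for ATF4 and 8.3e-05 for imprinted genes. With an estimated correlation the adjusted p = 0.0707, 0.119, 0.165, 0.165, 0.17 and 0.165, so none was called, and fry called G2/M, G1/S and imprinted genes. Fry in the blocked fit called 11 lists, among them fusion (adjusted p = 0.00382), the sarcomere (adjusted p = 0.00664), G2/M (adjusted p = 0.0141) and G1/S (adjusted p = 0.0331). Autophagy and lysosome, extracellular matrix and interferon-stimulated genes were called higher and chromatin regulator and ribosomal protein genes lower, with medians between -0.19 and 0.23 (adjusted p between 0.165 and 0.912 with an estimated correlation). The blocked fit also called ER chaperone genes (adjusted p = 0.0257) and adipocyte markers (adjusted p = 0.0451) lower, with an adjusted p = 0.431 and 0.284 with an estimated correlation in that fit.

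**Figure D3:**
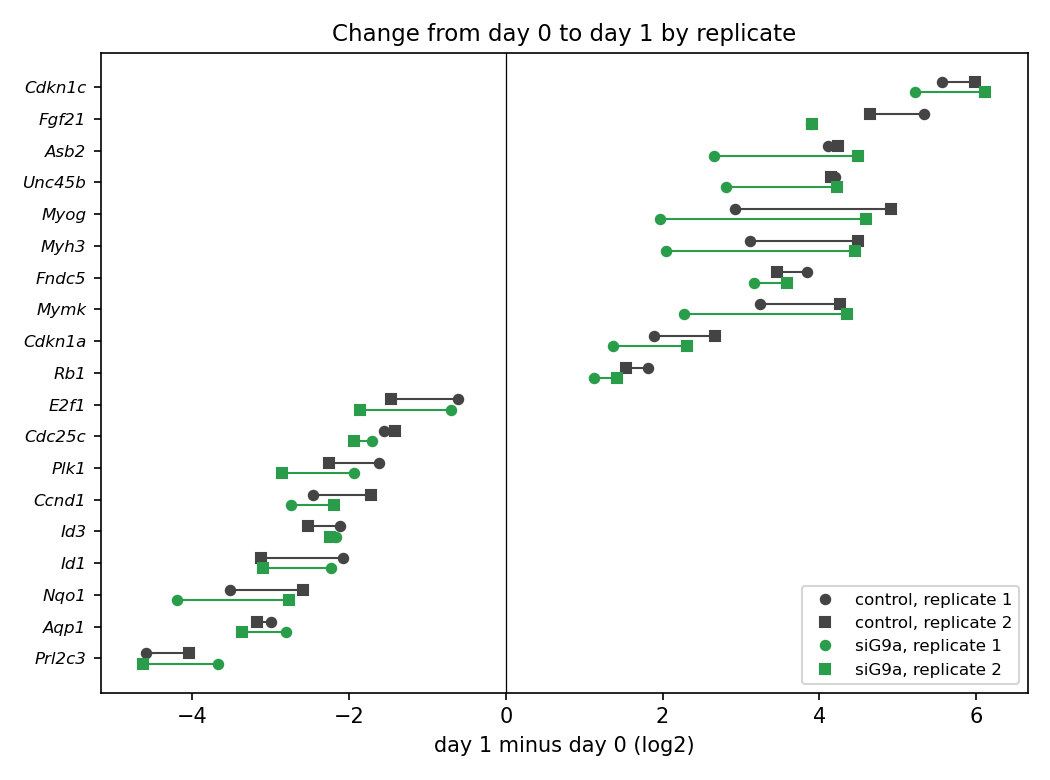
Day 1 minus day 0 (log2 units) for 19 genes in each replicate of control (grey) and siG9a (green) cells, with circles for replicate 1 and squares for replicate 2. Cdkn1c changed by 5.78 in control and 5.67 in siG9a cells, and Prl2c3 by -4.32 and -4.15.

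In siG9a cells the same change over time was compared with that in control cells. Cdkn1c rose by 5.67 ± 0.29, Asb2 by 3.57 ± 0.55, Fndc5 by 3.38 ± 0.46, Ramp2 by 3.15 ± 0.30 and Tgm2 by 2.70 ± 0.35, and Rtn4 (2.53 ± 0.21), Rgs16 (2.46 ± 0.35) and the Notch regulator gene Dtx4 (2.03 ± 0.23) were also among the largest rises. The proliferin genes Prl2c3 (-4.15 ± 0.26), Prl2c2 (-4.13 ± 0.29) and Prl2c4 (-3.94 ± 0.26) fell again, with Nqo1 (-3.48 ± 0.33), Aqp1 (-3.08 ± 0.30) and Id1 (-2.67 ± 0.35). The mitotic genes Cdc20 (-2.52 ± 0.43), Gtse1 (-2.49 ± 0.29), Plk1 (-2.40 ± 0.26) and Cdca3 (-2.38 ± 0.27), together with Ccnd1 (-2.46 ± 0.28), stood among the 12 largest falls. The G2/M list had a median of -1.55 (23 members called, 35 adjusted over the list alone) and G1/S one of -1.28 (13 called, 34 lower and 2 higher adjusted over the list alone). The sarcomere list had a median of 2.49 with all 48 members higher, 0 called over all features, 19 adjusted over the list alone and 33 in the blocked fit, with Myh3 at 3.25 ± 0.98 and Unc45b at 3.52 ± 0.77. The fusion list had a median of 0.92 (25 of 27 higher, 0 called, also 0 adjusted over the list alone, 16 higher and 1 lower in the blocked fit), and Myog stood at 3.28 ± 1.07, Cdkn1a at 1.84 ± 0.73, Rb1 at 1.27 ± 0.35 and Fgf21 at 3.90 ± 0.73.

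Limma called 285 features in siG9a cells, 72 higher and 213 lower, and the blocked fit 2825, among them all 285. The count was 4 without siG9a day 1 replicate 2, 11 without siG9a day 0 replicate 2, 55 without siG9a day 0 replicate 1, 81 without siG9a day 1 replicate 1 and 187 without either control day 0 array, and median centring gave 147, with 20 higher and 127 lower. Camera called 9 lists, with an adjusted p of 5.0e-56 for G2/M, 3.0e-41 for G1/S, 6.6e-21 for the sarcomere and 3.1e-06 for fusion. With an estimated correlation the adjusted p = 0.0524, 0.116, 0.302 and 0.302. Imprinted genes (median 0.20) and ATF4 genes (median 0.42) were called higher, with an adjusted p = 0.193 and 0.596 with an estimated correlation. Fry called G2/M, G1/S and imprinted genes. Fry in the blocked fit called 5 lists, fusion (adjusted p = 0.00566), the sarcomere (adjusted p = 0.0103), G2/M (adjusted p = 0.0138), imprinted genes (adjusted p = 0.0154) and germline genes (adjusted p = 0.0191), but not G1/S (adjusted p = 0.0503). Chromatin regulator, ribosomal protein and respiratory chain genes were called lower (adjusted p = 0.116, 0.756 and 0.756 with an estimated correlation), the last with a median of -0.12 but a mean of 0.00037, and the blocked fit added ER chaperone genes (adjusted p = 0.0441, and adjusted p = 0.552 with an estimated correlation in that fit). Of the features called in control and in siG9a cells, 66 rose and 168 fell in both, against 0.261 and 1.62 expected from independent draws, which samples of the same replicates are not. Across features the 2 changes, which share no arrays, correlated with a Pearson coefficient r = 0.883 and a Spearman coefficient of 0.518. They share replicate numbers, and their deviations between the replicates correlated with r = 0.537. Between control cells of 1 replicate and siG9a cells of the other, r was 0.672 and 0.649.

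The interaction asked whether the siG9a effect differed between the days. Limma called 0 features, with 18 at an unadjusted p under 0.05, and the blocked fit 0, with 1382, where chance alone gives 1572. Among the smallest p, none past the threshold, were Stom (0.70 ± 0.30), a membrane scaffold gene, Pramel37 (0.62 ± 0.27) and Serpinb9d (0.54 ± 0.24) on the higher side, and Ccdc80 (-0.60 ± 0.24), the heat shock protein gene Hspa2 (-0.60 ± 0.25) and Sugp1 (-0.57 ± 0.25) on the lower side. Camera called 7 of 29 lists, all lower at day 1 than at day 0, led by extracellular matrix (median difference -0.24, 37 of 44 members lower) and G2/M (-0.12, 35 of 51), each with an adjusted p of 1.4e-05. With an estimated correlation the adjusted p = 0.894 for extracellular matrix and 0.84 for G2/M, and fry called 0 lists. Median centring ended 5 of the 7 calls and kept those of these 2 lists. The blocked fit added fusion (adjusted p = 0.0374) and glycolysis genes (adjusted p = 0.0148), with an adjusted p = 0.508 and 0.791 with an estimated correlation in that fit. It then called no list in any of the 6 comparisons. The extracellular matrix difference turned to 0.12 without control day 0 replicate 1, 0.21 without siG9a day 1 replicate 1, 0.055 without siG9a day 0 replicate 2 and 0.12 without control day 1 replicate 2, and that of G2/M to 0.022 without control day 1 replicate 1 and 0.043 without siG9a day 1 replicate 2.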

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

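The interaction tests were set before the data were examined, whereas the tests of explanations in this part were chosen after the results were seen. The interaction over gene lists showed a siG9a effect that differed between the days for 7 lists, all lower at day 1 than at day 0 in camera. The median differences were -0.269 for sarcomere and contraction, -0.121 for G2/M and mitosis, -0.188 for p53 targets and DNA damage, -0.0738 for ATF4 and amino acid synthesis, -0.237 for extracellular matrix, -0.0708 for autophagy and lysosome and -0.0709 for the mitochondrial respiratory chain. Their adjusted p lay between 1.43e-05 and 0.00524, and between 0.84 and 0.989 with an estimated correlation, while fry gave an adjusted p of 0.983 for each. After median centring camera called 2 of them, G2/M (-0.197) and extracellular matrix (-0.313). Extracellular matrix genes were higher in siG9a at day 0 in both replicate pairs (0.23 and 0.11) and lower at day 1 in both (-0.084 and -0.031). P53 target genes had list medians of 0.084 and 0.14 at day 0 and 0.0089 and -0.038 at day 1. The G2/M and ATF4 lists were also lower at day 1 in both pairs. The sarcomere list went from 0.869 to 0.0284 in replicate 1 but from 0.141 to 0.202 in replicate 2. The respiratory chain list went from 0.156 to -0.0241 in replicate 1 but from -0.057 to -0.00921 in replicate 2. Autophagy and lysosome went from 0.131 to -0.043 in replicate 1 and from 0.0107 to 0.00813 in replicate 2.

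Mitotic genes were lower in siG9a cells at day 1. A constant offset between arrays was argued against by the G2/M median of -0.361 after median centring, still called by camera (adjusted p = 3.27e-10). Centring removes only such an offset, and a difference in spread between arrays was not tested. The day 1 array medians were -0.067 (control) and -0.049 (siG9a) in replicate 1 and 0.055 and 0.108 in replicate 2. Centring could therefore move the median of the G2/M list only a little. Without centring the list was not called at an adjusted p = 0.29 with an estimated correlation, and fry gave 0.992. A single deviating array was argued against by the replicate pair with the smaller shift, which shares no array with the other pair and stood at -0.29. The design offers G9a knockdown as a biological explanation, and 1 form of it, a uniform further advance along the change that all cells made from day 0 to day 1, was tested on features that rose by 1 unit or more in the control arrays of the other replicate. By the share that falling features had moved, the rising features would have stood at 0.159 and 0.152 in siG9a at day 1, but they stood at -0.00415 and 0.0326. The sarcomere list alone stood at 0.0284 in replicate 1, with 29 of 48 members higher, and at 0.202 in replicate 2, with 39 of 48 higher, so that a further advance of muscle genes alone stays open. A lower rate of division in the knockdown cells may account for the shift and stays open too, as does a rise that had already levelled off by day 1.

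Sarcomere genes were higher in siG9a cells at day 0. After median centring the list's median was 0.497 (adjusted p = 0.0262 in camera). The day 0 array medians were -0.069 (control) and -0.146 (siG9a) in replicate 1 and 0.038 and 0.034 in replicate 2. Centring could therefore move the list's median only a little, and this outcome was nearly fixed in advance. A constant offset as large as the list's median was not seen between these array medians. A difference in spread between arrays was not tested. Without centring the list was not called at an adjusted p = 0.809 with an estimated correlation. Its median turned to -0.432 without siG9a replicate 1, where the replicate difference also enters. A single deviating replicate pair stays open, because the list stood at 0.869 in replicate 1 and 0.141 in replicate 2, and the smaller value did not exceed the standard deviation between the pairs, although 36 of 48 members were higher in replicate 2 as well. An earlier start of the day 0 to day 1 change in siG9a cells may account for the pattern. Features that rose in the other replicate's control were higher in siG9a at day 0, by 0.338 and 0.0595, and those that fell were lower, by -0.196 and -0.0802. The rising features still included sarcomere genes, whose list median rose by 2.77 and 2.4 in control. The rising values are therefore not independent support, and the rising features without these genes were not tested. Whether knockdown or culture density brought this about was not tested.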

How the results depend on the processing

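Robust moderation, both feature filters, the mean of a gene's probes and every test of within-day pairs were chosen after seeing the data, and the other settings before the data were examined. Limma called 0 features for siG9a at day 0, at day 1 and for the interaction under every setting run, and 0 over both days except in tests of within-day pairs (256, with Ehmt2 at -1.50 past the threshold, against an adjusted p between 0.164 and 1 elsewhere). Over both days, 157 were called on these pairs after median centring, 569 with the replicate as a correlated block of these pairs (correlation -0.273) and 634 on the replicate means, where 1 residual degree of freedom left the variance to its prior. Changes over time varied in number. In control and in siG9a cells the called features came to 92 and 147 after median centring, 2775 and 2825 with the replicate block, 549 and 176 with array weights and 673 and 563 at an adjusted p under 0.10, and to 842 in siG9a cells on their own 4 arrays. The cause was not tested, except that the block removes the mean replicate difference over the groups. The part of that difference that changed between the days stays in. Replicate 2 minus replicate 1 was 0.103 at day 0 but -0.421 at day 1 for the G2/M median, and 0.178 but -0.384 for G1/S. The number of lists called at day 0, at day 1, over both days and for the interaction was 3, 4, 5 and 2 after median centring. An estimated correlation gave 0 lists in each of the 6 comparisons and fry gave 0 for siG9a and the interaction and 3 for each change over time (in the blocked fit 11 in control and 5 in siG9a cells). On the within-day pairs, camera with an estimated correlation called 0 lists, with a smallest adjusted p of 0.137. The correlation of the siG9a effects of both days was 0.228 in the upper part of the features by standard deviation and 0.181 in named features.

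Leaving out 1 array leaves a lone sample, assumed to vary like the other groups, and leaves its group without a partner for 1 replicate, so that the replicate difference enters the comparison. Counts over time then ranged from 7 to 363 in control and from 4 to 363 in siG9a cells, and called lists from 6 to 16 at day 0, 9 to 19 at day 1, 9 to 17 over both days, 10 to 17 in control and 4 to 15 for the interaction. At day 0, medians ranged from -0.432 to 1.7 for sarcomere, -0.194 to 0.618 for fusion and -0.135 to 0.48 for extracellular matrix, and genes from -0.824 to 0.00276 for Ccnd1, -0.253 to 1.86 for Actn3, -0.341 to 2.3 for Atp2a1, -1.05 to 2.37 for Myog and -0.961 to 2.14 for Myh3. At day 1 they ranged from -0.492 to 0.00918 for G1/S, -0.587 to 0.125 for cholesterol synthesis, -0.193 to 0.0376 for ribosomal proteins and -0.376 to 0.135 for ATF4. Over both days sarcomere ranged from -0.134 to 0.952, and the correlation of both days from -0.021 to 0.188. For the interaction the ranges were -0.345 to 0.0428 for G2/M, -0.547 to 0.208 for extracellular matrix, -1.41 to 0.601 for sarcomere, -0.309 to 0.135 for the respiratory chain and -0.388 to 0.147 for ATF4. G2/M at day 1 (-0.585 to -0.115) and the chosen medians over time kept their direction, as did Ehmt2 (-1.99 to -1.35 at day 0). With all arrays, 0 of 140 values of the 33 list medians chosen for the text and 0 of 1679 values of named genes changed direction under the other settings. The replicate block, the 1.5-fold minimum, the adjusted p under 0.10 and robust moderation leave every estimate unchanged. Under these no direction could turn, so both counts were partly fixed in advance. Over all lists and comparisons, median centring turned 35 of 174 medians, among them 1 over time in control and 7 in siG9a cells, and 0 of these lists were called with or without it. Background corrections, cyclic loess, detection filters, an intensity trend and the BeadChip as a block were not run, because they need the unmatched signal table or a chip name, and the signal over background that limits dim probes is unknown here.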

Other observations

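The test of within-day replicate pairs and the tests of explanations in this part were chosen after the data were seen, except the count over other groupings of the 8 arrays. The genes named here were chosen after their values were seen. The 4 within-day differences come from 2 biological replicates and were treated as independent, and their deviations between the replicates correlated over the days with r = 0.0412 across features. Some called genes differed mostly in replicate 1, such as Pvalb, by 1.05 and 1.82 there against 0.22 and 0.29 in replicate 2, or in replicate 2, such as Saa3, by 1.03 and 1.09 against 0.29 and 0.34. Among the 256 features called from these differences, the largest rise belonged to the predicted gene Gm5662, at 1.79 ± 0.10 (SE, n = 4 pairs, adjusted p = 4.55e-09 in limma), with both of its probes higher. Gsta3, a glutathione transferase, was higher by 1.07 ± 0.12 and Hsd11b1, which regenerates active glucocorticoid, by 0.94 ± 0.09, although 1 of the other probes of each went the other way. So were Ifitm1 (0.96 ± 0.12, with 4 of 5 probes higher), Gbp2 (0.78 ± 0.10), Alox5ap (0.76 ± 0.09), Plac8 (0.71 ± 0.08) and the acute-phase gene Saa3 (0.69 ± 0.11). The interferon-stimulated list had a median of 0.031 with 2 members called (adjusted p = 0.0153 in camera on the differences, adjusted p = 0.297 with an estimated correlation). Mb (0.79 ± 0.16), Klhl41 (0.64 ± 0.12), Tnnt3 (0.61 ± 0.11) and Actn2 (0.51 ± 0.11) were higher as well. Each of these 4 differed most in the day 0 pair of replicate 1, by 1.81, 1.32, 1.23 and 1.04, against values between 0.19 and 0.71 in the other pairs.

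The lower features included histone H2A genes, a group formed after the values were seen and not tested for enrichment. Of 16 measured H2ac genes 10 were called lower and 0 higher, with a median of -0.47, led by H2ac21 (-0.74 ± 0.08), H2ac11 (-0.70 ± 0.08) and H2ac22 (-0.60 ± 0.08), while 0 of 34 measured H2bc, H3c and H4c genes were called. H2ac genes are nearly alike in sequence, so their probes may not be independent, and this was not tested here. Caveolin 1 (Cav1) was lower by -0.68 ± 0.11, the growth factor pleiotrophin (Ptn) by -0.64 ± 0.10 with its second probe the other way, Casp6 by -0.61 ± 0.08 and the sterol demethylase gene Cyp51 by -0.52 ± 0.08. Camera on the differences called G1/S and G2/M lower (each adjusted p = 1.81e-23), with 7 and 9 members called, but each had an adjusted p = 0.137 with an estimated correlation and was then not called. Giving the 4 differences other signs is the matching test of chance: the real signs gave 256 features, the highest of the other 7 patterns gave 0, and 1 of 8 patterns reached the real count, but 8 patterns are too few for a share under 0.05. A constant offset between arrays was argued against as the whole source of these calls, since 157 features were called after median centring.

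For the comparison over both days without pairing, the 8 arrays were regrouped 4 against 4 with day kept in the model. The real grouping gave 0 called features, so that all 34 groupings necessarily gave as many and the comparison decides nothing. The highest of the others, 17336, came from the grouping of replicate 1 against replicate 2, which points to a structure of the samples, the difference between the replicates, unlike the 8 groupings that part all 4 within-day pairs as the real one does, which gave at most 0. With that difference as an additive term the blocked fit called 0 features, and the test of the 4 within-day differences called 256. The additive term leaves in the part of the replicate difference that changed between the days, which the within-day differences remove.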
